A study of Mus musculus with 2 samples.

How the data were processed

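The data came from CD4+ T cells that infiltrated the pancreas of 13 NOD mice, a strain that develops autoimmune diabetes. Per the labels' protocols, the mice were not diabetic and were 10 to 13 weeks old (10 weeks per the sample characteristics), and 55000 cells were sorted. Cells were sorted for CD90.2 and CD4 and for binding peptide-MHC tetramers in both fluorescent colours. The tetramers carried InsC-ChgA or InsC-IAPP, hybrid peptides of insulin C-peptide with a chromogranin A or an amylin fragment, or an insulin B chain peptide in 1 of 2 forms (InsB p8E and InsB p8G). Each of the 13 mice carried its own hashtag antibody and each of the 4 tetramers its own DNA barcode. All cells went into 1 pooled library of 10x 5' single-cell RNA sequencing, so mouse and specificity were not tied to different libraries. The labels' protocol names InsC-ChgA in 2 places of its tetramer list, so the barcodes of the hybrid peptides were matched to ChgA and IAPP from textbook knowledge of the T cell clones they are named after.

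Per the submitters' processing notes, Cell Ranger 6.1.2, kallisto, bustools 0.39.3, Seurat and the mouse genome build mm10 were used, and which tool made which file was not given in the sources used here. The gene matrix, the hashtag table and the tetramer table hold counts of unique molecular identifiers (UMIs), per the file headers and the deposited values, which are whole numbers. The deposited cell table gives the mitochondrial share of each cell as a fraction, per its values. It also holds deposited scores for 4 T cell programmes, called Tanergic, Tfh, Th1 and Treg by the authors, whose making was not given in the sources used here. The authors' cell table further gives a mouse, the tetramers a cell was positive for, and 1 of 13 clusters for each cell.

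The matrix held 32285 genes and 22309 barcodes, of which 14968 were in the deposited cell table and were used. Of the genes, 32158 were matched to a symbol in GENCODE release M21, which also gave the coordinates printed (mm10, counted from 1). The hashtag with the most counts was that of the deposited mouse in 99.8% of cells. The summed counts of a cell equalled its deposited total in 88.4% of cells, with a largest difference of 44 UMIs. A cell had a median of 1970 UMIs (500 to 37894) and a median of 1045 genes, and its mitochondrial share had a median of 0.783%. Cells with exactly 1 positive tetramer, 13074 in all, entered the comparisons. Mouse 7 had 7 cells, of which 5 had 1 tetramer, and was left out of every test.

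Cells are not replicates, so counts were summed per mouse and specificity. Sums of at least 10 cells were kept, which gave 47 libraries from 12 mice, since mouse 13 had too few InsB p8E cells. A library held 34080 to 5669380 UMIs. Genes were kept by edgeR's filterByExpr, which left 5606, scaled by TMM, and tested with edgeR 4.0.16's robust quasi-likelihood F test. The model had the 4 specificities and the mouse as a block, 32 residual degrees of freedom and a common biological coefficient of variation of 0.130. The same animals gave every specificity, so the mouse number pairs the libraries. InsC-ChgA was compared with the mean of the other 3 specificities, which averages log values, and all pairs were compared with each other. Comparisons with InsB p8E rest on 11 mice. P-values were two-sided and adjusted by Benjamini-Hochberg within a comparison, with a threshold of 0.05. CPM are counts per 1e6 UMIs, as means of the libraries.

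Of 18 gene lists, 16 had at least 5 tested members and were tested with limma 3.58.1's camera on voom values, with a preset correlation of 0.01, and again with an estimated correlation and with fry. The lists of Th17 and Th2 genes had too few. Members were counted from the edgeR table and were also adjusted over the list alone. Variable segment genes of the T cell receptor were taken from the same table and adjusted over all genes and over the segments alone. Cluster shares, scores, quality measures and shares of specificities were computed per mouse and tested with two-sided exact sign-flip permutation tests, whose smallest possible p is 0.000488 for 12 mice and 0.000977 for 11. The rule for naming genes was this. Against the mean, the 12 largest rises and 12 largest falls were taken among genes past the threshold with an average log2 CPM of at least 5 and the same direction in at least 75 percent of mice. For pairs, the 4 largest each way were taken. Receptor segments, ribosomal, mitochondrial, Gm and Rik genes were left out. The up to 4 members of each list with the smallest p, the 3 highest and 3 lowest V segments and 14 genes of T cell identity were taken whatever their p. Against the mean the text prints all 14 and the others that passed. For pairs it prints most of those that passed and leaves out some with small changes. Of the genes ranked by change, 1 is not reported here.

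On simulated counts for the 5606 genes of the comparison with the mean, the test recovered 98 of 100 genes changed by 1 on the log2 scale and 96 of 100 changed by 2, with 11 false calls. For lists, real counts with labels shuffled within mice were used, with 1 list raised by 0.5 on the log2 scale in the InsC-ChgA group. Camera with the preset correlation recovered 16 of 16 raised lists and called 62 of 240 others. Lists share members, so some of these others held raised genes too. The estimated correlation was not run there. In shuffles with no list raised, a median of 3 lists passed that comparison with the preset correlation and 0 with the estimated one. The estimated correlation therefore decides here which list results are held.

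The comparisons, their tests, the lists, the naming rule and most alternatives were chosen before the data were examined. These alternatives were DESeq2 1.42.0, size factors in place of TMM, no filter on low counts, no block, 5 or 20 cells per library, equal cell numbers within a mouse, stricter and rebuilt tetramer calls, clusters removed, own Leiden clusters and each mouse left out. The strict call needed 5 times the next tetramer's tag count and at least 10 counts, and kept 12689 cells. The rebuilt call needed 3 times and 5 counts, gave 13359 cells and the same specificity in 100.0% of the cells called both ways. Chosen after the data were seen were thinning each cell to 500 UMIs, which left out no cell, the removal of clusters 5 and 10, of cluster 6, of clusters 2, 6 and 7, of the 5 percent of cells with the highest doublet scores and of the 182 cells with a CD8 UMI, the clusterings made without called genes, and the list tests with an estimated correlation and no block together. Scrublet marked 1 of 14968 cells as a doublet, so removing it tests little, and doublets were weighed by other tests. Whether doublets had been removed before the cell table was deposited was not given in the sources used here. An own cluster was matched to a deposited one at a Jaccard index of at least 0.5. Shares in own clusters were adjusted over the matched clusters alone, so over fewer tests than the 52 of the deposited clusters. Own clusters used 2000 variable genes, 30 components and 15 neighbours in scanpy 1.11.5. R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9 and matplotlib 3.10.9 were used.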

Results

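Gene expression was measured in 14968 CD4+ T cells from the pancreas of 13 NOD mice, with 7 to 3748 cells per mouse. By the deposited tetramer calls, 8322 cells bound InsC-ChgA alone, 2514 InsC-IAPP alone, 777 InsB p8E alone and 1461 InsB p8G alone. A further 1340 cells were positive for 2 tetramers, 62 for 3 and 492 for none. The cells held 45617597 UMIs, and a mouse held 18509 to 9686438. Cells with 1 tetramer held 23552573 UMIs in the InsC-ChgA group, 7001366 in the InsC-IAPP group, 2697601 in the InsB p8E group and 5213026 in the InsB p8G group. Their median UMIs per cell were 1864.5, 1806, 2407 and 2185 in that order. Tetramer tags were well apart from their background: the median InsC-ChgA tag count was 398 in positive and 7 in negative cells, and that of InsB p8G, the weakest, was 147 and 4.

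InsC-ChgA was the most frequent of the 4 specificities in all 12 mice with enough cells. It made up 60.5% ± 11.6 of the cells with 1 tetramer (mean and SD, n = 12 mice, range 38.3 to 73.9). InsC-IAPP, the other hybrid peptide, made up 18% ± 6.98. Each form of the insulin peptide made up less when taken alone, with InsB p8G at 13.7% ± 5.40 and InsB p8E at 7.83% ± 5.46. The 625 cells positive for both InsB tetramers alone are outside these shares. The shares therefore do not rank insulin B binding as a whole against InsC-IAPP. The InsC-ChgA share was higher than each of the others in 12 of 12 mice, with exact sign-flip p = 0.000488 in each of 3 tests, which is the smallest possible and 0.000488 after adjustment. The cells had been sorted on tetramer binding, so these are shares of sorted cells, which the staining and the sort also set.

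**Figure D1:**
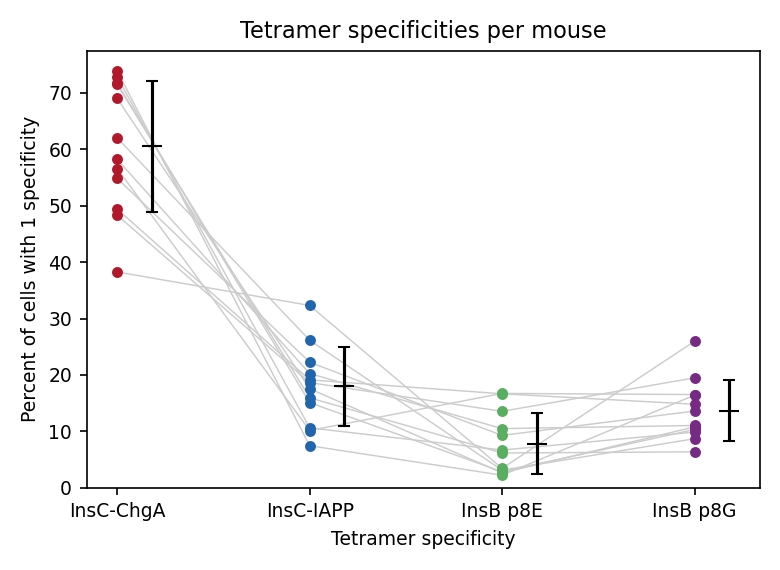
Percent of the cells with 1 tetramer that had each specificity, with a point and a line per mouse (n = 12) and the mean ± SD beside the points. InsC-ChgA lies at 38.3 to 73.9 percent and above the other specificities in every mouse shown.

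The comparison named in the series title sets InsC-ChgA cells against the cells of the other specificities. InsC-ChgA cells held more transcripts of chemokine and cytotoxic genes. Ccl5, a chemokine of effector lymphocytes (ENSMUSG00000035042, chromosome 11, 83525778 to 83530518), was 4.06-fold higher than the mean of the others (log2 fold change 2.02 ± 0.31 (SE), 12 of 12 mice, adjusted p = 6.64e-05). Its mean level was 3177 CPM in InsC-ChgA cells against 858 in InsC-IAPP, 1114 in InsB p8E and 609 in InsB p8G cells. Gzmk, a granzyme protease (ENSMUSG00000042385, chromosome 13, 113171608 to 113225908), was 3.86-fold higher (log2 1.95 ± 0.22, 12 of 12 mice, adjusted p = 6.61e-07). Penk, the precursor of enkephalin peptides, was 2.73-fold higher (log2 1.45 ± 0.31, 12 of 12 mice, adjusted p = 0.00329). The chemokine genes Ccl4 (1.33 ± 0.29), Ccl3 (1.2 ± 0.25) and Xcl1 (1.21 ± 0.34) rose as well, on the log2 scale, in 11, 11 and 12 of 12 mice, with adjusted p from 0.0028 to 0.0279. Fasl, the ligand that triggers the death receptor Fas, rose by 0.83 ± 0.16, and Themis, a regulator of T cell receptor signalling, by 0.92 ± 0.14. Ier3 (1.22 ± 0.21), an immediate early gene, rose too. Cxcl13 (1.46 ± 0.39), which attracts B cells, and Tgfbr3 (0.84 ± 0.14) passed against the mean, but their mean CPM was higher in InsC-IAPP cells (74.7 and 71.8) than in InsC-ChgA cells (42.7 and 68.1). St6galnac2 rose by 0.88 ± 0.13, with uncertain identity because 2 gene IDs share its symbol.

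The genes that fell in InsC-ChgA cells included several that insulin-specific cells held at higher levels. Pglyrp1, a peptidoglycan-binding protein (ENSMUSG00000030413, chromosome 7, 18871331 to 18890459), had the largest fall of the ranked genes (2.29-fold lower, log2 -1.2 ± 0.24, 11 of 12 mice, adjusted p = 0.00196). It stood at 27.7 CPM in InsC-ChgA and 30.8 in InsC-IAPP cells, against 109 in InsB p8E and 105 in InsB p8G cells. Ikzf2, which encodes the transcription factor Helios of regulatory T cells, fell by 0.82 ± 0.20 (9 of 12 mice, adjusted p = 0.0118), with 150 CPM against 153, 368 and 393. Ddit4, a stress-induced inhibitor of mTOR signalling, fell by 0.84 ± 0.15 in 12 of 12 mice, and Ets2, a transcription factor, by 0.74 ± 0.11 in 11. Prdx4, a peroxidase of the endoplasmic reticulum, fell by 0.69 ± 0.09 (11 of 12 mice, adjusted p = 6.61e-07). The other ranked falls were Art2b (-0.77), Areg (-0.74), Serpina3g (-0.65), the interferon gamma receptor gene Ifngr1 (-0.60), the chemokine receptor gene Ccr2 (-0.58), Il6st (-0.55) and Podnl1 (-0.52), with adjusted p up to 0.0473.

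In all, 192 genes were higher and 110 lower in InsC-ChgA cells than in the mean of the others, of 5606 tested by edgeR. Several genes of T cell identity did not pass the test against the mean: Tbx21 (0.10), Cxcr3 (-0.14), Cxcr6 (0.22), Bcl6 (0.13), Il21 (0.26), Il10 (0.07), Tcf7 (0.36), Pdcd1 (0.25), Lag3 (-0.21), Izumo1r (-0.21), Nt5e (-0.30) and Mki67 (-0.35), with adjusted p from 0.113 to 0.897. Foxp3, the master regulator of regulatory T cells, was at -0.51 ± 0.41 (adjusted p = 0.56; -0.88 without mouse 11 and 0.02 without mouse 4), since the mean of the others joined 2.89 CPM in InsC-IAPP cells with 105 and 194 in the insulin groups. InsC-ChgA cells also differed in quality measures: their median UMIs were 1991 ± 231 (SD) against 1985, 2420 and 2223 in the other groups (lower than their mean in 9 of 12 mice, exact p = 0.00586, adjusted 0.0381 over 13 measures). Of the other measures the CD8 T cell markers alone passed, while cell cycle phases, mitochondrial share and markers of B, myeloid, NK, acinar, islet, red and stromal cells had adjusted p from 0.182 to 0.984. Without clusters 2, 6 and 7, the rises of Ccl5 (0.85, adjusted p = 0.102), Penk (0.98), Ccl4 (0.73), Ccl3 (0.51) and Fasl (0.51) did not pass, and Areg turned to 0.17 with equal cells within a mouse. The count of genes was 37 with equal cells, 90 with equal UMIs, 152 without mouse 10, 196 without the block, 711 without a filter and 922 (837 higher) by DESeq2.

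**Figure D2:**
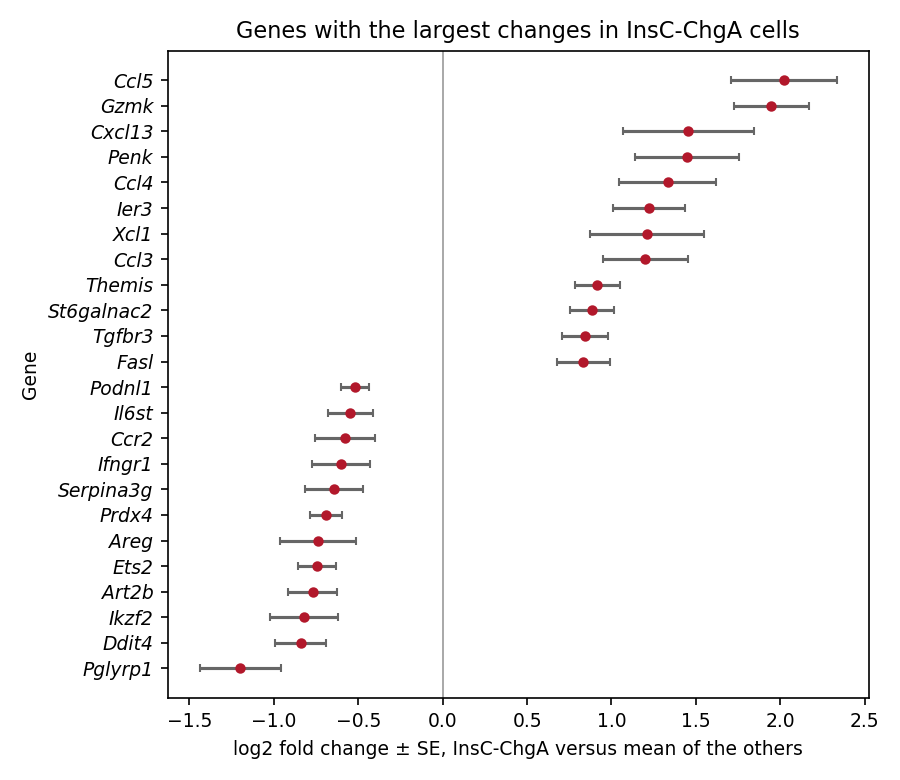
Log2 fold change ± SE (horizontal axis) of the 12 largest rises and 12 largest falls in InsC-ChgA cells against the mean of the other specificities (n = 12 mice), among genes with an average log2 CPM of at least 5, receptor segments left out. Of the genes shown, Ccl5 and Gzmk rise most (2.02 and 1.95) and Pglyrp1 falls most (2.29-fold lower).

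Cytokines and TNF family ligands rose together in InsC-ChgA cells: 6 of 17 measured members of 26 listed were higher and 0 lower, and 9 were higher when adjusted over the list alone (camera adjusted p = 1.22e-07, and adjusted p = 0.00771 with an estimated correlation). Ifng, the Th1 cytokine, rose by 0.81 ± 0.19 in 12 of 12 mice. Its difference was largest against InsB p8G cells (1.66 to 1.92 with 1 mouse left out). Against InsB p8E cells it was 0.42 to 0.64, and against InsC-IAPP cells 0.05 to 0.24. Th1 effector genes rose: 6 of 16 members were higher and 0 lower, and 7 were higher and 2 lower adjusted over the list alone (adjusted p = 2.39e-06, and adjusted p = 0.0197 with an estimated correlation), though Tbx21, which encodes the Th1 regulator T-bet, did not pass. Cytotoxic genes rose: 5 of 8 members were higher, among them Nkg7 (0.60 ± 0.15), and 1 was lower, against 5 and 2 adjusted over the list alone (adjusted p = 6.78e-05, and adjusted p = 0.0231 with an estimated correlation). The summed level of CD8 T cell markers, a list that holds Gzmk itself, moved with these groups, at 321 ± 241 CPM in InsC-ChgA cells against 169, 89.9 and 95.6 (higher in 11 of 12 mice, exact p = 0.00439, adjusted 0.0381). Genes of recent T cell receptor signalling rose: 5 of 24 members were higher, including Nr4a2 (0.76 ± 0.14), Spry1 (0.70 ± 0.14), Jun (0.47 ± 0.12) and Tnfaip3 (0.26 ± 0.07), and 8 were higher and 1 lower adjusted over the list alone (adjusted p = 1.37e-05, and adjusted p = 0.0481 with an estimated correlation, which was 0.0673 without the block). Stem-like memory genes rose: 2 of 10 members, Xcl1 and the lymph node homing receptor gene Ccr7 (0.69 ± 0.17), were higher, and 4 adjusted over the list alone (adjusted p = 0.00553, and adjusted p = 0.0467 with an estimated correlation, which was 0.0565 without the block). Some of these lists share members that rose. Ifng, Fasl, Ccl3, Ccl4 and Ccl5 are in both the cytokine and the Th1 effector list. Ccl5, Fasl and Nkg7 are in both the Th1 effector and the cytotoxic list, and Xcl1 is in the cytokine and stem-like lists. The results of these lists are therefore not independent of each other.

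Glycolysis genes fell in InsC-ChgA cells: 3 of 15 measured members were lower and 0 higher, and 4 were lower adjusted over the list alone (adjusted p = 1.37e-05, and adjusted p = 0.0467 with an estimated correlation). Slc16a3, which exports lactate (ENSMUSG00000025161, chromosome 11, 120948480 to 120960868), fell by 1.31 ± 0.18 in 12 of 12 mice (adjusted p = 1.25e-06), at 8.28 CPM against 13.4, 47.5 and 30.2. Ldha (-0.35 ± 0.06), which makes lactate, and Pkm (-0.23 ± 0.05), which makes pyruvate, fell in 11 and 12 of 12 mice. Against single groups the list was held for InsB p8E, and not for InsC-IAPP or InsB p8G. As given below, Slc16a3 and Ldha were also lower in InsC-IAPP cells than in both insulin groups. The fall is therefore not shown to be particular to InsC-ChgA cells.

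The other lists were not held. For regulatory T cell genes, 1 of 13 members, Nrp1 (0.69 ± 0.17), was higher and 3, Il2ra (-0.93 ± 0.19), Ikzf2 and Areg, were lower, against 1 and 5 adjusted over the list alone (adjusted p = 1.49e-05 for a fall, but adjusted p = 0.0728 with an estimated correlation). For T follicular helper genes, Sostdc1 was lower (-2.15 ± 0.45, 11 of 12 mice; adjusted p = 0.00268) and Sh2d1a higher (0.48 ± 0.11), with 3 and 1 of 15 higher and lower adjusted over the list alone. That list had adjusted p = 0.0462, and adjusted p = 0.241 with an estimated correlation, and its mean (0.02) lay far below its median (0.20). Anergy genes had 2 of 12 members higher, Dgkz (0.38 ± 0.08) and Ikzf1 (0.31 ± 0.08), and 7 higher and 1 lower adjusted over the list alone (adjusted p = 0.0107, but adjusted p = 0.141 with an estimated correlation). Tissue residency genes had Cd44 (0.36 ± 0.08) and Itga4 (0.34 ± 0.08) higher and Ahr (-0.45 ± 0.10) lower, of 13, and 4 and 1 adjusted over the list alone (adjusted p = 0.0158, but adjusted p = 0.152 with an estimated correlation). Naive and central memory genes had 1 of 12 higher, and 6 higher and 1 lower adjusted over the list alone (adjusted p = 0.00638, but adjusted p = 0.11 with an estimated correlation). Stress genes of dissociation and heat shock had 3 of 14 higher, Ier3, Jun and Dnajb1 (0.27 ± 0.08), and 5 adjusted over the list alone (adjusted p = 0.00647, but adjusted p = 0.118 with an estimated correlation).

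None of the 26 proliferation genes and none of the 25 oxidative phosphorylation genes passed, over all genes or adjusted over the list alone. Both lists lay lower by camera (adjusted p = 2e-05 and 0.00565), but had adjusted p = 0.241 and adjusted p = 0.19 with an estimated correlation. Inhibitory receptor and exhaustion genes had 1 of 11 members higher, Nr4a2, and 1 adjusted over the list alone, and interferon response genes had 0 of 17 either way by edgeR (Ly6a, with the smallest p, at -0.94 ± 0.30, adjusted p = 0.059). For both lists camera gave adjusted p = 0.088. The Th17 and Th2 lists had too few measured members to test, and Rora (-0.28) and Gata3 (0.19) did not pass.

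The cells' deposited clusters address which T cell states each specificity held. Cluster 4, whose leading genes were Itgae, Foxp3, Gzmb, Ly6a and Ecm1, was rare among InsC-ChgA cells and common among InsB p8G cells. It held 5.83% ± 4.02 (SD, n = 12 mice) of InsC-ChgA, 5.40% ± 4.10 of InsC-IAPP, 19.0% ± 21.9 of InsB p8E (11 mice) and 35.5% ± 16.8 of InsB p8G cells. Against InsB p8G cells the InsC-ChgA share was lower in 12 of 12 mice, by a mean of 29.6 points (difference -29.6, exact p = 0.000488, the smallest possible, adjusted 0.00508), and against the mean of the others in 11 of 12 mice (-13.9, adjusted p = 0.00846 by the exact test). Against InsB p8E (adjusted p = 0.06) and InsC-IAPP (adjusted p = 0.832) it did not pass. In all, 20 of 52 tests of cluster shares passed after adjustment. Shares of clusters 0, 2, 6, 7, 9 and 11, which also passed in some comparisons, are not given, since genes that lead them differed between the groups and own clusters did not match them, with or without the called genes. For cluster 12 the test against InsB p8E cells is among those that passed (higher in 7 of 11 mice, lower in 0, exact test, adjusted p = 0.0406). It rests on 23 InsC-ChgA cells and a count of 0 of 774. The 95% interval of that count reaches 0.494% and covers the InsC-ChgA share of 0.276%. That interval pools cells over mice, so it does not test the paired difference. When cells were clustered without the 302 genes called against the mean, a cluster with a Jaccard index of 0.554 to cluster 4 held 6.37% of InsC-ChgA, 0.546% of InsC-IAPP and 39.5% of InsB p8G cells, and InsC-ChgA was then higher than InsC-IAPP in 11 of 12 mice (adjusted p = 0.00781). Foxp3 and Itgae stayed among the genes used there, and without all 1101 genes called in any comparison cluster 4 was not recovered (0.212), so its share and those genes are not independent results.

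**Figure D3:**
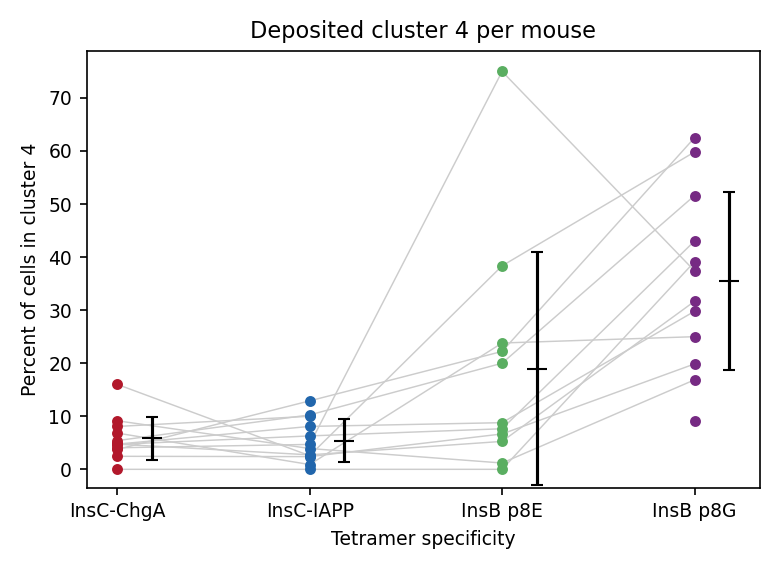
Percent of each specificity's cells in deposited cluster 4, with a point per mouse (n = 12, and 11 for InsB p8E), lines joining the points of a mouse and the mean ± SD beside them. InsB p8G has the highest mean (35.5) and InsC-ChgA and InsC-IAPP have low means (5.83 and 5.40).

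Cycling cells were fewer among InsC-ChgA cells, though not past the threshold against the mean. Cluster 3, led by the replication genes Pclaf and Rrm2, held 8.14% ± 2.95 of InsC-ChgA cells and 12.9% ± 4.91 of the mean of the others (-4.80, lower in 10 of 12 mice, exact p = 0.0225, adjusted 0.0556). Against InsC-IAPP cells it passed (-4.39, lower in 9 of 12 mice, exact p = 0.00684, adjusted 0.0209), and against InsB p8G (adjusted 0.0656) and InsB p8E cells (adjusted 0.374) it did not. Without the 302 genes, a cluster with a Jaccard index of 0.752 gave -4.01 (adjusted p = 0.0469 by the exact test), and without all 1101 genes one of 0.774 gave -4.51 (adjusted 0.082). Both were adjusted over the matched clusters alone, so over fewer tests, and cannot be set against the 0.0556 above. The deposited Th1 score of InsC-ChgA cells was higher than the mean of the others, at -0.0471 against -0.181, in 12 of 12 mice (difference 0.134, exact test, adjusted p = 0.0026). Their deposited Treg score was lower, at 0.0249 against 0.131, in 10 of 12 mice (adjusted p = 0.00625 by the exact test), and their Tanergic score was lower, at 0.0410 against 0.111 (adjusted 0.0104). Against InsC-IAPP cells alone neither score passed, with a Treg score of 0.0249 against 0.00174 (higher in 7 of 12 mice, adjusted 0.367) and adjusted 0.592 for Tanergic. The Tfh score did not pass against the mean (adjusted 0.0739).

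Receptor genes differed by specificity, which checks the tetramer calls, since the receptor is what a tetramer binds. Trav16d-dv11 was 5.76 ± 0.41 higher on the log2 scale in InsC-ChgA cells than in the mean of the others (12 of 12 mice, adjusted p = 1.26e-11), at 259 CPM against 13.4, 4.26 and 2.08. Trbv15 rose by 4.71 ± 0.38 (adjusted p = 1.98e-10) and reached 2654 CPM against 27.7, 453 and 219. Trbv20 rose by 3.05 ± 0.46. Trav5-4 was lower in InsC-ChgA cells (-4.41 ± 0.51), at 25.4 CPM against 491, 585 and 725, and so was Trav10 (-2.73 ± 0.70). Trbv31, among the 3 lowest, did not pass (-3.40, adjusted p = 0.0706). Between pairs, Trbv15 was 6.61 ± 0.63 higher in InsC-ChgA than in InsC-IAPP cells, which held more Trav10 (-4.52 ± 0.63) and Trbv17 (-4.33 ± 0.94). InsC-IAPP cells held more Trbv19 than InsB p8E (4.60 ± 1.07) and InsB p8G cells (2.77 ± 0.76). Trav2 was higher in InsB p8E than in InsC-ChgA cells (-4.62 ± 0.82), though in 6 of 11 mice. Trbv1 was 5.35 ± 0.80 higher in InsB p8E than in InsB p8G cells, at 891 CPM, and so was Trav13n-4 (3.86 ± 0.98). Trbv5 (-4.52 ± 0.46) and Trbv2 (-3.21 ± 0.58) were higher in InsB p8G than in InsC-ChgA cells, in 12 of 12 mice. Of 18 measured segments, 7 passed against the mean over all genes and 10 adjusted over the segments alone. Segments share sequence with near-identical copies, so the identity of each is uncertain.

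Cells of the 2 hybrid peptides differed in few genes. InsC-ChgA cells held more Ccl5 than InsC-IAPP cells (3.47-fold, log2 1.79 ± 0.42, 10 of 12 mice, adjusted p = 0.03) and more Csf1, a growth factor of macrophages (1.26 ± 0.30, 12 of 12 mice, adjusted p = 0.0346). They also held more Foxp3 (2.72 ± 0.67, 10 of 12 mice, adjusted p = 0.0467) and Rln3 (4.82 ± 1.16, adjusted p = 0.041), which had 29 and 5 UMIs over all InsC-IAPP cells, and Foxp3 was at 4.12 without mouse 4. InsC-IAPP cells held more of the inflammatory caspase genes Casp1 (-0.79 ± 0.16) and Casp4 (-0.75 ± 0.14, 12 of 12 mice, adjusted p = 0.000771), more Sccpdh (-0.78 ± 0.12, 12 of 12 mice, adjusted p = 1.14e-05) and more Art2b (-0.78 ± 0.18). Cytotoxic genes were higher in InsC-ChgA cells: 2 of 8 members were, and 6 adjusted over the list alone (camera adjusted p = 4.8e-11, and adjusted p = 0.000217 with an estimated correlation). Nkg7, a protein of cytotoxic granules, rose by 0.85 ± 0.20. The Th1 effector (2 of 16 higher, and 4 adjusted over the list alone), cytokine (2 of 17, and 4), stem-like memory (0 of 10, and 4) and inhibitory receptor lists (0 of 11, and 3) were higher as well, with adjusted p = 0.0259, 0.0317, 0.0328 and 0.0259 with an estimated correlation. Without the block the Th1 effector (0.0818) and inhibitory receptor lists (0.0722) lost that call. The Th1 effector and cytokine lists share Ccl5 and Fasl with the cytotoxic list. Regulatory T cell genes lay higher by camera (adjusted p = 4.32e-05), but had adjusted p = 0.102 with an estimated correlation. In all, 18 genes were higher and 15 lower by edgeR. The calls of Foxp3, Rln3 and Csf1 were each lost with at least 20 cells per library and without any of 10 or 11 of the 12 mice, and Ccl5 lost its call without clusters 2, 6 and 7. The count was 7 with equal cells within a mouse, 14 with equal UMIs, 13 without mouse 10, 233 without a filter and 140 by DESeq2.

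Against InsB p8E, InsC-ChgA cells again held more Gzmk (8.25-fold, log2 3.04 ± 0.39, 11 of 11 mice, adjusted p = 8.04e-06). Ccl5 (1.84 ± 0.44), Themis (1.14 ± 0.22) and Nsg2 (1.21 ± 0.33) rose too, though Nsg2 lost its call when most single mice were left out, and Ccl5 when some were. Regulatory T cell genes were lower: 0 of 13 members were higher and 3, with Il2ra (-1.31 ± 0.26), Ikzf2 (-1.12 ± 0.26) and Areg (-1.26 ± 0.32), lower, and 9 were lower adjusted over the list alone (camera adjusted p = 7.91e-10, and adjusted p = 0.0179 with an estimated correlation, which was 0.0568 without the block). Glycolysis genes were lower: 3 of 15 were, and 6 adjusted over the list alone (adjusted p = 1.78e-06, and adjusted p = 0.0321 with an estimated correlation), with Slc16a3 at -2.14 ± 0.25, Ldha at -0.40 ± 0.08 and Tpi1 at -0.54 ± 0.13. Sostdc1, an inhibitor of BMP and Wnt signalling, fell by 3.13 ± 0.58 in 11 of 11 mice (adjusted p = 0.00152). Csf1 (-1.09 ± 0.28), the aryl hydrocarbon receptor gene Ahr (-0.68 ± 0.14) and the granule proteoglycan gene Srgn (-0.26 ± 0.06) fell too. Pglyrp1 (-1.59 ± 0.34), Ecm1 (-1.43 ± 0.29), Ddit4 (-1.34 ± 0.20) and the ectonucleotidase gene Nt5e (-0.69 ± 0.19) fell, and Foxp3 did not pass (-1.55, adjusted p = 0.0507). In all, 60 genes were higher and 67 lower in 11 mice. The count was 14 with equal cells within a mouse, 37 with equal UMIs, 70 without the block, 84 without cluster 4, 82 without mouse 10, 65 without mouse 11, 382 without a filter and 521 by DESeq2.

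InsC-ChgA and InsB p8G cells differed in more genes than any other pair, among them genes of regulatory T cells. Foxp3 (ENSMUSG00000039521, chromosome X, 7573644 to 7595245) was 6.44-fold lower in InsC-ChgA cells (-2.69 ± 0.33, 11 of 12 mice, adjusted p = 5.25e-07), at 40.0 ± 34.5 CPM (SD) against 194 ± 75.3. The integrin gene Itgae (-2.39 ± 0.35), Ecm1 (-2.21 ± 0.22), Ly6a (-2.20 ± 0.34) and the interleukin 2 receptor gene Il2ra (-1.64 ± 0.21) were lower as well. Of 13 measured regulatory T cell genes 9 were lower and 1 higher, and 10 and 1 adjusted over the list alone (camera adjusted p = 5.89e-11, and adjusted p = 0.0143 with an estimated correlation). InsC-ChgA cells held more Spp1, which encodes osteopontin (3.26 ± 0.71, and 4.62 without mouse 5), Cxcl13 (2.87 ± 0.59), Ccl5 (2.43 ± 0.42) and Ier3 (2.21 ± 0.33). Ifng was 3.39-fold higher (1.76 ± 0.26, 12 of 12 mice, adjusted p = 1.42e-05), and Pdcd1, which encodes the receptor PD-1, rose by 0.82 ± 0.12. Il21 (0.97), Tcf7 (0.56) and Tbx21 (0.41) rose, and Izumo1r (-0.54) and Cxcr3 (-0.31) fell, with adjusted p from 0.009 to 0.0306. Th1 effector genes (10 of 16 higher, 3 lower, and 11 and 3 adjusted over the list alone), genes of recent receptor signalling (15 and 2 of 24, and 17 and 3) and cytokines (12 and 2 of 17 both ways) were higher, with adjusted p = 0.0308, 0.0363 and 0.0143 with an estimated correlation. Without the block the first 2 of these lists had 0.0709 each and lost that call. The Th1 effector and cytokine lists share members such as Ifng and Ccl5. In all, 488 genes were higher and 408 lower. With equal cells within a mouse 195 passed, with equal UMIs 156, and Spp1, Il21, Tbx21, Tcf7, Cxcr3 and Izumo1r each lost their call in some settings.

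Further members of the lists changed between InsC-ChgA and InsB p8G cells. Of genes induced by receptor signalling, Spry1 (1.44 ± 0.19), Nr4a2 (1.3 ± 0.19), Jun (0.87 ± 0.15), Dusp2 (0.77 ± 0.14), Nr4a3 (0.71 ± 0.17), Zfp36 (0.51 ± 0.15) and Egr1 (0.43 ± 0.13) were higher. Of cytotoxic and effector genes, Ccl3 (2.13 ± 0.38), Xcl1 (1.86 ± 0.51), Gzmk (1.78 ± 0.28), Fasl (1.68 ± 0.24) and Stat4 (0.80 ± 0.14) were higher, whereas Gzmb (-2.14 ± 0.40) and Hopx (-1.54 ± 0.25) were lower. The anergy genes Tbc1d4 (1.28 ± 0.23), Dgkz (0.57 ± 0.10), Nfatc1 (0.54 ± 0.10) and Cblb (0.44 ± 0.10) and the follicular helper genes Tox2 (0.89 ± 0.20), Cd200 (0.76 ± 0.17) and Sh2d1a (0.65 ± 0.14) were higher. The adhesion genes Itgb1 (0.99 ± 0.19), Cd44 (0.55 ± 0.10) and Itga4 (0.51 ± 0.10), the survival gene Bcl2 (0.81 ± 0.21), Ms4a4b (0.79 ± 0.17) and Tox (0.50 ± 0.11) rose. Satb1, a chromatin organiser (-1.94 ± 0.25), Areg (-1.35 ± 0.26), Lef1 (-0.43 ± 0.14) and the costimulatory receptor gene Tnfrsf4 (-0.44 ± 0.08) fell. Slc16a3 (-1.54 ± 0.23), Ldha (-0.62 ± 0.07) and Pkm (-0.36 ± 0.07) fell and Hif1a rose (0.28 ± 0.08). The interferon response genes Ifi209 (-0.60 ± 0.15), Gbp7 (-0.57 ± 0.13) and Ifi27l2a (-0.25 ± 0.09) fell, as did the cycling genes Cdk1 (-0.67 ± 0.23), Ccnb1 (-0.58 ± 0.20), Mcm2 (-0.53 ± 0.15) and Mcm5 (-0.53 ± 0.18). Of respiratory chain genes, Ndufb8 and Sdhb (-0.26 each), Uqcrq (-0.19) and Ndufa4 (-0.18) fell by little. In all, 5 of 17 interferon response genes, Ly6a included, 4 of 26 proliferation genes and 4 of 25 respiratory chain genes fell, and none of these 3 lists was held (adjusted p = 0.144, 0.249 and 0.226 with an estimated correlation). Glycolysis, anergy, follicular helper, tissue residency, cytotoxic and stress lists were not held either (adjusted p = 0.0668, 0.108, 0.144, 0.144, 0.182 and 0.182 with an estimated correlation). Each gene named had adjusted p up to 0.0442 by edgeR.

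InsC-IAPP cells held almost no Foxp3 transcripts. Foxp3 was 42.3-fold lower than in InsB p8G cells (-5.40 ± 0.55, 12 of 12 mice, adjusted p = 7.99e-08) and 19.2-fold lower than in InsB p8E cells (-4.27 ± 0.69, 10 of 11 mice, adjusted p = 0.000435). These folds rest on 29 Foxp3 UMIs in InsC-IAPP cells, with none in 7 of 12 libraries, and without mouse 4 the log2 values were -6.74 and -5.56. Regulatory T cell genes were lower than in InsB p8G cells (10 of 13, and 11 lower and 1 higher adjusted over the list alone; adjusted p = 0.00127 with an estimated correlation) and than in InsB p8E cells (8 of 13, and 12 adjusted over the list alone; adjusted p = 0.000455 with an estimated correlation). Itgae fell by 4.66 ± 0.56 and 3.57 ± 0.72, and the granzyme gene Gzmb by 4.15 ± 0.57 and 3.09 ± 0.71, in the same order. Rln3 (-6.49 ± 1.03 and -6.43 ± 1.12) had 5 UMIs in InsC-IAPP cells. Cxcl13 was higher in InsC-IAPP than in InsB p8G (3.70 ± 0.57) and InsB p8E cells (3.17 ± 0.68, and 5.02 without mouse 8). Igfbp7 (2.19 ± 0.36), the cell cycle inhibitor gene Cdkn2a (2.12 ± 0.26) and Nrgn (2.05 ± 0.47) rose against InsB p8G, as did Ifng (1.61 ± 0.27), Il21 (1.31 ± 0.27), Pdcd1 (0.71 ± 0.13), Tcf7 (0.60 ± 0.19) and Tbx21 (0.47 ± 0.15). Tesc (1.21 ± 0.13, 11 of 11 mice, adjusted p = 9.21e-10), Gpr25 (1.27 ± 0.23) and Gzmk (2.03 ± 0.42) rose against InsB p8E. By edgeR 280 genes were higher and 245 lower than in InsB p8G cells, and 45 and 65 than in InsB p8E cells. With equal cells within a mouse these counts were 146 and 33, with equal UMIs 100 and 18, and without mouse 11, 314 and 61. Against InsB p8E the count was 59 without cluster 4, 300 without a filter and 222 by DESeq2.

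Other list members set InsC-IAPP cells apart from both insulin groups. Csf1 was lower than in InsB p8G (-2.27 ± 0.31, 12 of 12 mice) and InsB p8E cells (-2.34 ± 0.35, 11 of 11 mice). The receptor genes Il2ra (-1.80 ± 0.25 and -1.47 ± 0.30), Tnfrsf9 (-1.51 ± 0.31 and -1.85 ± 0.34), Tnfrsf4 (-0.55 ± 0.08 and -0.39 ± 0.09) and Cd27 (-0.97 ± 0.17 and -0.86 ± 0.19) fell, and so did Areg (-1.74 ± 0.32 and -1.65 ± 0.38), Satb1 (-2.68 ± 0.32 and -1.65 ± 0.43) and the protease inhibitor gene Cst7 (-0.99 ± 0.16 and -0.91 ± 0.18). Slc16a3 (-1.29 ± 0.26 and -1.88 ± 0.28) and Ldha (-0.58 ± 0.07 and -0.35 ± 0.08) were lower, while Tox2 (1.22 ± 0.21 and 0.92 ± 0.24) and Foxp1 (0.63 ± 0.13 and 0.65 ± 0.16), transcription factors, were higher. Against InsB p8G, Tnfsf11 (1.44 ± 0.27), Fasl (1.32 ± 0.27), Spry1 (1.23 ± 0.20), Itgb1 (1.11 ± 0.20), Tbc1d4 (1.05 ± 0.24), Egr2 (0.93 ± 0.23), Tnf (0.89 ± 0.17), Stat4 (0.79 ± 0.15) and Btla (0.70 ± 0.18) rose, and Ly6a (-2.50 ± 0.37), Hopx (-1.82 ± 0.30), Ccr8 (-0.64 ± 0.17) and the checkpoint receptor gene Ctla4 (-0.59 ± 0.13) fell. Inhibitory receptor genes were lower than in InsB p8E cells (1 of 11, and 4 adjusted over the list alone; adjusted p = 0.0338 with an estimated correlation, which was 0.194 without the block). Beside that list and the regulatory T cell genes, no list was held in these 2 comparisons.

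The insulin peptides' cells were set apart by cytokine and inhibitory receptor genes. InsB p8E cells held more Pdcd1 than InsB p8G cells (2.01-fold, log2 1.01 ± 0.14, 10 of 11 mice, adjusted p = 1.60e-05) and more Ifng (1.24 ± 0.30). Spp1 (4.40 ± 0.73), Nrgn (2.94 ± 0.48), Igfbp7 (1.93 ± 0.42) and Tnfsf8, a TNF family ligand (1.70 ± 0.35), were higher, and the chemokine receptor gene Ccr2 (-1.01 ± 0.28), Arl5a (-0.91 ± 0.21) and Ifi209 (-0.82 ± 0.22) lower. Ccr2 lost its call without any of mice 1, 2, 3, 5, 8, 9, 10 and 13 (-0.65 without mouse 10), Ifi209 without any of mice 4, 5, 8, 9 and 10, Ifng without mouse 2, 8 or 10, and Arl5a without mouse 10. Inhibitory receptor genes (3 of 11 higher, and 5 adjusted over the list alone) and cytokines (5 of 17 higher, and 10 adjusted over the list alone) each had adjusted p = 0.00852 with an estimated correlation, and no other list was held. Without the block the inhibitory receptor list lost that call (0.129). Nr4a2 (0.99 ± 0.24), Tox (0.50 ± 0.14), Tnfsf11 (1.45 ± 0.30) and Fasl (1.22 ± 0.34) were among the members that rose. Nrp1 (1.44 ± 0.33), a receptor of regulatory T cells, Tbc1d4 (1.26 ± 0.26), Spry1 (0.99 ± 0.22), Bhlhe40 (0.97 ± 0.20), Stat4 (0.80 ± 0.16), Cd200 (0.77 ± 0.19), Jun (0.69 ± 0.18), Nfatc1 (0.52 ± 0.12), Hif1a (0.34 ± 0.09) and Junb (0.34 ± 0.09) rose as well, and S1pr1, which guides exit from tissue, fell by 0.72 ± 0.18. Foxp3 did not pass (-1.13, adjusted p = 0.135). In all, 94 genes were higher and 27 lower. The count was 33 with equal cells within a mouse, 30 with equal UMIs, 251 with rebuilt tetramer calls and 63 without the block. It was 40, 47 and 58 without mouse 10, 8 and 5, 211 without mouse 6, 382 without a filter, and 323 by DESeq2, of which 221 were lower.

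On average over mice, InsB p8E and InsB p8G tetramers shared more of the cells positive for either than other pairs did. Of 3280 cells positive for either, 677 were positive for both. Per mouse the share was 17.4% ± 15.9 (SD, n = 12, range 2.14 to 55.9), against a mean of 1.53% ± 0.50 for the other 5 pairs (12 of 12 mice, exact p = 0.000488, the smallest possible). InsC-ChgA with InsC-IAPP, the next pair, had 2.69%, with 365 cells positive for both over all mice. A pair of groups of unequal size, such as InsC-ChgA with InsB p8E, cannot reach a high share of this kind. The size of the contrast therefore depends on group sizes as well as on binding. In mouse 5 the 2.14% lay below InsC-ChgA with InsC-IAPP (3.31%) and InsC-IAPP with InsB p8G (2.45%). With cells called positive at 5 or more tag counts the difference turned to -16.5, and at 10 or more it was 4.59 (exact p = 0.287), thresholds near the background medians of 7 and 9 for the hybrid peptide tags.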

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

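The tests of cells outside the comparisons, those negative for every tetramer or positive for several, were chosen after the data were seen. Of 28 groups of 7 to 9 mice, 5 had a mouse whose gap to the nearest other mouse, over the whole range, was above the 95% critical value of Dixon's test, which chance alone marks in about 1 in 20 groups. In mouse 3, cells positive for tetramer combinations other than InsB p8E with InsB p8G held 2.83 times the median UMIs of its cells with 1 tetramer, the highest of 7 mice. Of the cells positive for both InsB tetramers, cluster 5 held 17.6% in mouse 1, which is 3 cells of 17, the highest of 8 mice. Cluster 12 held 0.833% in mouse 11, which is 1 cell of 120, and none in the 7 other mice, so this mark rests on that cell. Of the cells positive for other combinations, cluster 7 held 0% in mouse 8, the lowest of 9 mice, and cluster 9 held 3.70% in mouse 12, the highest of 9.

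Cells negative for every tetramer, 492 in all, lay in some clusters more than cells with 1 tetramer did, and no comparison of the report used them. Cluster 9, led by Igfbp4 and Ccr7, held 18.6% ± 8.06 (SD, n = 11 mice) of them against 2.24% of cells with 1 tetramer (11 of 11 mice higher, exact p = 0.000977, the smallest possible, adjusted 0.0305 over 39 tests). Cluster 12, led by Jchain and the MHC class II genes H2-Aa and H2-Ab1 of antigen-presenting cells, held 4.50% ± 3.31 against 0.338% (10 of 11 mice, adjusted 0.0305). Cluster 5, led by Lars2 and Fosl2, held 8.11% ± 2.91 against 4.25% (9 of 11 mice, adjusted 0.0305). Cluster 3 held fewer of the negative cells, 4.99% against 9.84% (adjusted 0.0305). So did cluster 7, with 0.836% against 4.13% (higher in 1 of 11 mice, adjusted 0.0305 by the exact test). Own clusters did not match clusters 5, 7 and 9 (Jaccard index at most 0.176, 0.0899 and 0.281), so these shares hold for the deposited clusters alone. Whether genes that lead them differ in negative cells was not tested. For cells positive for several tetramers the smallest adjusted p was 0.0762 by the exact test.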

How the results depend on the processing

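Chosen after the data were seen were thinning, the removal of clusters 5 and 10, of cluster 6, of clusters 2, 6 and 7, of cells with a CD8 UMI and of high doublet scores, clustering without called genes, and an estimated correlation without the block; all other settings were planned. The shares per specificity gave the same calls in 9 of 9 settings and comparisons, and V segment counts stayed within 1.5 times in 7 of 7 comparisons with the strict call. Of named genes, 4650 values kept their direction and side of the threshold, 290 lost and 62 gained a call, and 1 reversed: Areg, InsC-ChgA versus the mean, at 0.17 with equal cells. Among cluster shares, 792 kept their call, 30 gained and 22 lost one. Counts of genes not named below stayed within 1.5 times.

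The counts of genes, in the order of InsC-ChgA versus the mean, InsC-IAPP, InsB p8E and InsB p8G, InsC-IAPP versus InsB p8E and InsB p8G, and InsB p8E versus InsB p8G, were 302, 33, 127, 896, 110, 525 and 121. With cells thinned to equal UMIs they were 90, 14, 37, 156, 18, 100 and 30 of 1092 tested, and with equal cells within a mouse 37, 7, 14, 195, 33, 146 and 33 of 2668, both with fewer genes tested. DESeq2 called 922 (837 higher, 85 lower), 140 (124 and 16), 521 (448 and 73), 222 (130 and 92, InsC-IAPP versus InsB p8E) and 323 (102 and 221, InsB p8E versus InsB p8G); its median log2 fold change of all genes was 0.12 in InsC-ChgA versus InsB p8E, and 249 of the 302 genes were shared. In InsC-ChgA versus InsB p8G it called 929 higher and 383 lower, against 488 and 408. No filter gave 711 (539 and 172), 233 (167 and 66), 382 (239 and 143), 300 (117 and 183) and 382 (199 and 183) in the same comparisons, with 17480 tested in place of 5606. For DESeq2 the cause was not tested. RLE size factors called 308, of which 295 were shared.

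With no replicate block, counts fell to 196 against the mean, 70 in InsC-ChgA versus InsB p8E and 63 in InsB p8E versus InsB p8G, 5 lists passed with the preset correlation in InsC-ChgA versus InsB p8E, and 13 of 72 named genes with a call lost it. Rebuilt calls gave 251 genes in InsB p8E versus InsB p8G. Without cluster 4, 84 and 59 genes were called in InsC-ChgA and InsC-IAPP versus InsB p8E. The cause was not tested for these. With an estimated correlation 6, 5, 4, 2, 1 and 2 lists passed (InsC-ChgA versus the mean, InsC-IAPP and InsB p8G, InsC-IAPP versus InsB p8E and InsB p8G, InsB p8E versus InsB p8G), against 14, 8, 13, 4, 9 and 11 with the preset one, and fry passed 5 in InsC-ChgA versus InsC-IAPP. With no replicate block and an estimated correlation together, 4, 3, 1, 2, 1, 2 and 1 lists were held in the 7 comparisons, against 6, 5, 2, 4, 2, 1 and 2; a list was gained in InsC-IAPP versus InsB p8G alone, and the cause was not tested. Among single lists under an estimated correlation, fry or no block, 270 values kept their call, 56 lost and 10 gained one.

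Leaving out each mouse gave 152 to 322, 13 to 34, 65 to 135, 674 to 1035, 61 to 132, 314 to 571 and 40 to 211 genes in the order above. The count moved by over 1.5 times without mouse 10 (152, 13, 82 and, for InsB p8E versus InsB p8G, 40), mouse 11 (65 in InsC-ChgA, 61 and 314 in InsC-IAPP comparisons), and, for InsB p8E versus InsB p8G, mice 5 (58), 8 (47) and 6 (211). The cause was not tested. Calls of named genes were lost against the mean for Areg (mice 1, 3, 4, 8, 9, 10, 11, 12), Ccr2 (1, 2, 3, 4, 8, 9, 10, 12, 13), Ifngr1 (4, 8, 9, 10, 12), Serpina3g (4, 6, 10, 12), Xcl1 (1, 3, 4, 6, 8, 10) and Cxcl13 (4, 10). In InsC-ChgA versus InsC-IAPP they were lost for Ccl5 (3, 4, 6, 10, 12, 13), Art2b (10, 12) and Casp1 (10), and versus InsB p8E for Ccl5 (3, 4, 6, 10), Nsg2 (1, 2, 3, 4, 5, 6, 8, 11, 12), Nt5e (2, 4, 5, 10, 11, 12) and Pglyrp1 (11). In InsC-ChgA versus InsB p8G they were lost for Tcf7 (1, 2, 5, 8, 9, 10, 11, 12, 13), Tbx21 (3, 8, 11, 12), Izumo1r (4) and Cxcr3 (11). In InsC-IAPP comparisons they were lost for Tcf7 (1, 2, 3, 5, 8, 9, 11, 12, 13) and Tbx21 (3, 8, 9, 11, 12) versus InsB p8G, and Gzmb (11, 12) and Cxcl13 (11) versus InsB p8E.

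Co-binding was -16.5 at 5 or more and 4.59 at 10 or more tag counts, since thresholds that low let in background tags. The cluster 3 share of InsC-ChgA cells against the mean, -4.80 and short of the threshold, passed at -4.79 with the strict call, -4.80 with no replicate block, -4.34, -4.20 and -4.15 in own clusters at resolutions 0.4, 0.8 and 1.2, -4.01 without called genes, -5.76 without mouse 2 and -5.33 without mouse 4 (range -5.76 to -3.84). Own clusters, with or without called genes, were adjusted over the matched clusters alone, so over fewer tests. Their differences were smaller than that of the deposited cluster, so these passes do not strengthen the result. For the other settings the cause was not tested. Depth limits what can be tested, since libraries held as few as 34080 UMIs in InsC-IAPP and 44058 in InsB p8E cells.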

Other observations

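Every test within single clusters, and the CD8, depth, single-mouse, background-tag and gene-count split tests below, were chosen or worded after the results were seen, and for the doublet test the median UMIs of cells with several tetramers had been seen. Differences by specificity were also seen among cells of the same cluster. The fits in clusters 0, 1, 3 and 4 had 28, 33, 27 and 26 libraries. The specificity with the fewest had 4, 7, 3 and 3 of them. In cluster 1, led by Nsg2, Sostdc1 and Tcf7, InsC-ChgA cells held more Gzmk (3.53 ± 0.36 (SE), adjusted p = 1.37e-06) and Ccl5 (2.46 ± 0.28, adjusted p = 6.62e-06) than the mean of the others, and less Art2b (-1.25 ± 0.20). There 61 genes were higher and 28 lower, and 49 of these 89 were also called in the comparison of all cells. In cycling cells of cluster 3, Gzmk was higher too (2.55 ± 0.46), while Ccl5 did not pass (2.26 ± 0.56, adjusted p = 0.13), and Lag3, an inhibitory receptor gene, lower (-0.57 ± 0.11). Neither passed in cluster 0, the largest (Gzmk 0.91, adjusted p = 0.14; Ccl5 0.58, adjusted p = 0.413), or in cluster 4 (Gzmk 2.17, adjusted p = 0.158; Ccl5 0.61, adjusted p = 0.93). With so few libraries this does not show like levels. Cycling InsC-ChgA cells held less Foxp3 than cycling InsB p8G cells (-2.27 ± 0.35, adjusted p = 0.00104), with 83 genes higher and 89 lower. Clusters were made from the same cells, so these sets are not independent of the genes.

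Cells of the Foxp3-rich cluster 4 also differed by specificity, in 26 libraries with as few as 3 of a specificity. InsC-ChgA cells of cluster 4 held more Il21, a cytokine of follicular helper cells (3.43 ± 0.39, adjusted p = 1.82e-07), more Ifng (1.78 ± 0.41) and more Pdcd1 (1.03 ± 0.21) than InsB p8G cells of cluster 4. They held less Ikzf2 (-1.19 ± 0.18, adjusted p = 0.000321) and Pglyrp1 (-1.89 ± 0.32), while Foxp3 was at -1.03 ± 0.37 and did not pass (adjusted p = 0.146), which does not show like levels. In that comparison 40 genes were higher and 54 lower, of which 79 were shared with the comparison of all cells. With cluster 4 removed, a planned setting, InsC-ChgA and InsB p8G cells differed in 1241 genes, of which 659 were shared with the 896 called with it.

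The first pattern weighed was the rise of chemokine and cytotoxic genes in InsC-ChgA cells. Against CD8 T cells among the sorted cells, Cd8a plus Cd8b1 made up 2.52% of the Cd4 level in cluster 2, where Ccl5, Nkg7 and Gzmk lead. Against unequal depth for Ccl5, Gzmk, Penk and Ccl4, their median rise with cells thinned to equal UMIs was 0.830 of that without, while the 8 others had too few UMIs left to test and stay open. For more cells of clusters 2, 6 and 7, whose sizes are not given here, 7 of the 12 rises passed without these clusters, between the bounds set, with all 12 positive and a median of 0.86 against 1.22, so a shift in cell states and a change within states cannot be told apart for the 5 lost. The rise may in part be a property of InsC-ChgA cells of some states, a hypothesis found on these data.

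The second pattern was the larger share of cluster 4 among InsB p8G cells. Against weak staining of unspecific cells, the InsB p8G cells with tag counts above the median of their mouse exceeded InsC-ChgA cells by 25.8 points (11 of 12 mice, exact p = 0.00146), though they lay 7.68 points below those with lower counts (difference -7.68, higher in 4 of 12 mice, exact p = 0.112), so a part from staining stays open. Against unequal depth, the log2 ratio of mean Foxp3 CPM was -1.97 with equal UMIs and -2.30 without thinning, a measure taken after Foxp3 fell out of the tested genes, on 106 and 138 UMIs. Against 1 expanded clone in 1 mouse, the difference nearest 0 with a mouse left out was -27.0 points. More cluster 4 cells among InsB p8G cells may be a property of the specificity, a hypothesis, and tetramer affinity or the sort were not tested. The cluster 4 share does not measure regulatory T cells alike in all groups. It was 5.40% of InsC-IAPP and 5.83% of InsC-ChgA cells, while mean Foxp3 with equal UMIs was 4.78 and 44.8 CPM.

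The third pattern was InsB p8E and InsB p8G tetramers on the same cells. Against doublets, cells with both held 0.972 ± 0.265 (SD, n = 8 mice) times the median UMIs of cells with 1 InsB tetramer, while cells with other combinations held 2.20 ± 0.306 times those of cells with 1 tetramer (7 mice). A background InsB p8G tag on InsB p8E cells and receptors that bind both forms of the peptide, a candidate explanation, cannot be told apart: the tag count of cells with both was 30.5 times that of InsB p8E cells (58 against 18.5 in mouse 1), but the call rests on that same tag. Cells with both did not differ from either group in any gene by edgeR at 8 mice, which does not show like levels. At an unadjusted p under 0.05 were 91 of 2890 tested genes against InsB p8E and 340 of 4052 against InsB p8G.

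The splits shuffled all 4 specificities within mice, so they ask whether the 4 groups together are alike. Real differences of a group add spread to every shuffled fit, so the splits cannot exclude chance for a single comparison. For gene counts, 1 of 100 splits, the real one, gave as many in all 7 comparisons, which excludes chance for the 4 groups together. In the order InsC-ChgA versus the mean, InsC-IAPP, InsB p8E and InsB p8G, InsC-IAPP versus InsB p8E and InsB p8G, and InsB p8E versus InsB p8G, the real counts were 302, 33, 127, 896, 110, 525 and 121 and the highest others 4, 3, 2, 15, 2, 1 and 0. The same held (1 of 100) for V segments, with 7, 7, 5, 9, 6, 7 and 3 called and at most 1 in another split. For lists with the preset correlation, 14, 8, 3, 13, 4, 9 and 11 passed, the highest others were 12, 12, 13, 14, 12, 11 and 12, and 1, 14, 56, 2, 50, 6 and 4 of 100 splits gave as many. Even for the 4 groups together, chance was thus not excluded by the counts of InsC-ChgA versus InsC-IAPP and InsB p8E. The same held for InsC-IAPP versus InsB p8E and InsB p8G. With an estimated correlation 6, 5, 2, 4, 2, 1 and 2 passed, the highest others were 3, 3, 3, 3, 1, 3 and 1, and 1, 1, 3, 1, 1, 6 and 1 splits gave as many. Here the count of InsC-IAPP versus InsB p8G alone did not exclude chance for the 4 groups together.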
